A study of Mus musculus with 12 samples.

How the data were processed

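Gene expression was measured in the livers of 12 mice aged 8 weeks, with 1 array per animal and no pooling of animals. The samples were grouped by sex and by the genotype given in the labels, which made 4 groups of 3 animals: male WT, male KO, female WT and female KO. KO animals carried floxed Jak2 alleles and a Cre recombinase driven by the albumin promoter, and WT animals were their littermate controls. Both came from a mixed C57Bl/6:129Sv background and were fed breeder chow. Animals are named by group and by the number in the labels. The labels used here do not give the litter of an animal, so animals could not be paired by litter and were treated as unpaired.

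Total RNA was extracted with TRIZOL and purified on RNeasy columns, then amplified and labelled with biotin in the Affymetrix whole-transcript workflow, per the labels' protocols. The arrays were processed in Affymetrix Expression Console, per the submitters' processing notes. The summary and normalization algorithm, its version and the annotation are not given in the sources used here. The deposited values are log2 probe set summaries: they ran from 1.22 to 14.82, and the 12 array medians lay between 5 and 5.07. No scanner output was used here, so background correction and summary could not be repeated. On arrays of this kind the number of arrays limits the precision.

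The value table had 35557 probe sets. The platform's probe table gave 1 gene symbol for 21789 of them, several symbols for 1621 and no gene for 12147. Probe sets with several symbols or none were left out of the comparisons and were looked at separately. Entrez identifiers of 21698 probe sets were matched to a current gene table, which changed 0 symbols. For each of the 999 genes with more than 1 probe set, the probe set with the highest mean over the 12 arrays stood for the gene. This left 19938 genes, all of which were tested with no filter on dim probe sets.

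The deposited log2 values were used without further scaling. A linear model with 4 group means was fitted to each gene with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The 4 groups shared 1 estimate of the spread, with 8 residual and 6.42 prior degrees of freedom. There were 6 contrasts: KO against WT in males, KO against WT in females, the mean of these differences over the sexes, their difference (males minus females), and males against females in WT and in KO. A gene was called when its p adjusted by Benjamini and Hochberg over the 19938 genes was under 0.05. All p-values are two-sided unless stated otherwise. The tests, the contrasts, the threshold, the gene lists, the naming rule and the alternatives named in this part were chosen before the data were examined, apart from the exceptions given where they occur.

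For each contrast the text could name up to 10 genes that rose most and up to 10 that fell most among called genes whose groups had non-overlapping ranges. The range condition was not used for the mean over the sexes or for the difference between them. Up to 4 called genes with the largest change could be named per gene list and contrast. Jak2, Igf1, Igfals, Socs2, Cish, Ghr, Cd36, Pparg, Fasn, Scd1, Srebf1, Xist, Eif2s3y, Kdm5d and Uty were named whatever their values, and Ddx3y was on that list but was not among the genes measured. Predicted genes without a characterised product were skipped when the 10 were chosen.

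There were 29 fixed gene lists, covering growth hormone targets, sex-biased liver genes, pathways of hepatocyte metabolism, stress and immune responses, and markers of cells other than hepatocytes. For each list and contrast the called members were counted over all genes and again adjusted over the list alone. The lists were tested against all other genes with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with a correlation estimated from the residuals and the rotation test fry were run beside it. A sex index was computed per animal as the mean of the male-biased list minus the mean of the female-biased list, each on log2 values centred per gene over the 12 arrays. Groups of 3 were compared on it by an exact permutation test, whose smallest two-sided p is 0.1. Called genes within 10 Mb of Jak2 were compared with all other genes by Fisher's exact test, with gene order from the GRCm38.p6 gene table. Genes called in both sexes were set against the number expected for independent lists, with a one-sided hypergeometric p.

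The alternatives were quantile normalization, centring each array on its median, leaving out the 33.3% of genes with the lowest mean, a trended and a robust variance prior, array weights, every probe set tested on its own, the mean of a gene's probe sets, only the arrays compared, at least a 2-fold change, an adjusted p under 0.01, and leaving out each animal in turn. After the values were seen, the naming rule, the list tests and the overlap of the sexes were also applied to the fit without male KO 207.

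The procedure was tested on simulated data with known changes for the male contrast, on 19938 genes in 5 runs. It recovered 36.4% of genes changed by 0.5 log2, 91.6% of those changed by 1, 98.8% of those changed by 2 and 100% of those changed by 3. It called a mean of 9.4 unchanged genes per run. The recovered shares do not carry over to genes with a wide spread within male KO. In the real male contrast Hsd3b5 differed by -3.99 (limma, adjusted p = 0.174) and Egfr by -3.25 (limma, adjusted p = 0.122). Neither was called. Their SD was 3.36 and 2.41 in male KO, against 0.18 and 0.16 in male WT. Cyp4a14, with an SD of 1.24 in male KO, was called. These genes were singled out after their values were seen. Of simulated lists without a change, 2.07% had a camera p under 0.05. Genes were simulated as independent of each other, so this share does not hold for real lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with pandas 2.3.3.

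Parts of this processing could affect the values. Probe sets of closely related genes, such as those of the Cyp2b, Cyp4a, Sult2a, Sult3a and Mup families, can bind each other's transcripts, so the values of single members are uncertain. For genes with several probe sets these did not always move by the same amount: the Socs2 probe set used here changed by -3.62 in females, and the other one by -1.34. Array values near the lower end are compressed, so fold changes of dim genes are understated. Array summaries give no absolute transcript number, and levels of different genes were not compared with each other.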

Results

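Liver expression of 19938 genes was measured in 12 mice aged 8 weeks, 3 in each of 4 groups: male WT, male KO, female WT and female KO. JAK2 is the kinase that passes on the signal of the growth hormone receptor, mainly to the transcription factor STAT5, and the labels describe deletion of its gene in hepatocytes only. Values are deposited log2 probe set summaries, and 1 unit is a 2-fold difference. Changes are differences of group means with their standard error (SE) and limma's adjusted p, with n = 3 animals per group throughout, and the number of arrays limits their precision.

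Jak2 itself (probe set 10462363) was not lower in the animals labelled KO. It read 6.49, 6.56 and 6.18 in male WT 112, 116 and 126, and 6.97, 6.86 and 6.65 in male KO 114, 122 and 207. In females it read 6.50, 6.88 and 6.89 in WT 119, 132 and 147, and 6.61, 6.71 and 7.09 in KO 102, 131 and 141. The difference was 0.42 (SE 0.15, adjusted p = 0.386) in males and 0.05 (SE 0.15, adjusted p = 0.972) in females. Which part of Jak2 was deleted is not given in the sources used here, and a probe set that spans the rest of the transcript can still give signal, so this value checks no genotype label. The sex labels could be checked. Xist, transcribed from the inactive X chromosome, read 9.90 to 10.52 in the 6 females and 3.51 to 4.47 in the 6 males. The Y-linked gene Eif2s3y read 6.85 to 7.38 in males and 2.67 to 3.02 in females. The Y-linked genes Kdm5d and Uty were higher in males by 2.04 and 3.06 (log2) in WT and by 2.14 and 3.39 in KO.

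Array quality was even, and 1 animal stood apart from its group. Correlations between arrays lay between 0.979 and 0.992, and no pair of arrays was identical. The first principal component held 31.7% of the variance. Male KO 114 and 122 lay at 18.56 and 18.53 on it and the male WT animals at -24.97 to -19.18. Male KO 207 lay at -15.42, beside male WT. Its mean correlation was 0.991 with the male WT arrays and 0.984 with the other male KO arrays. All comparisons below include this animal, and values without it are given for many of the results that differ, but not for all.

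**Figure D1:**
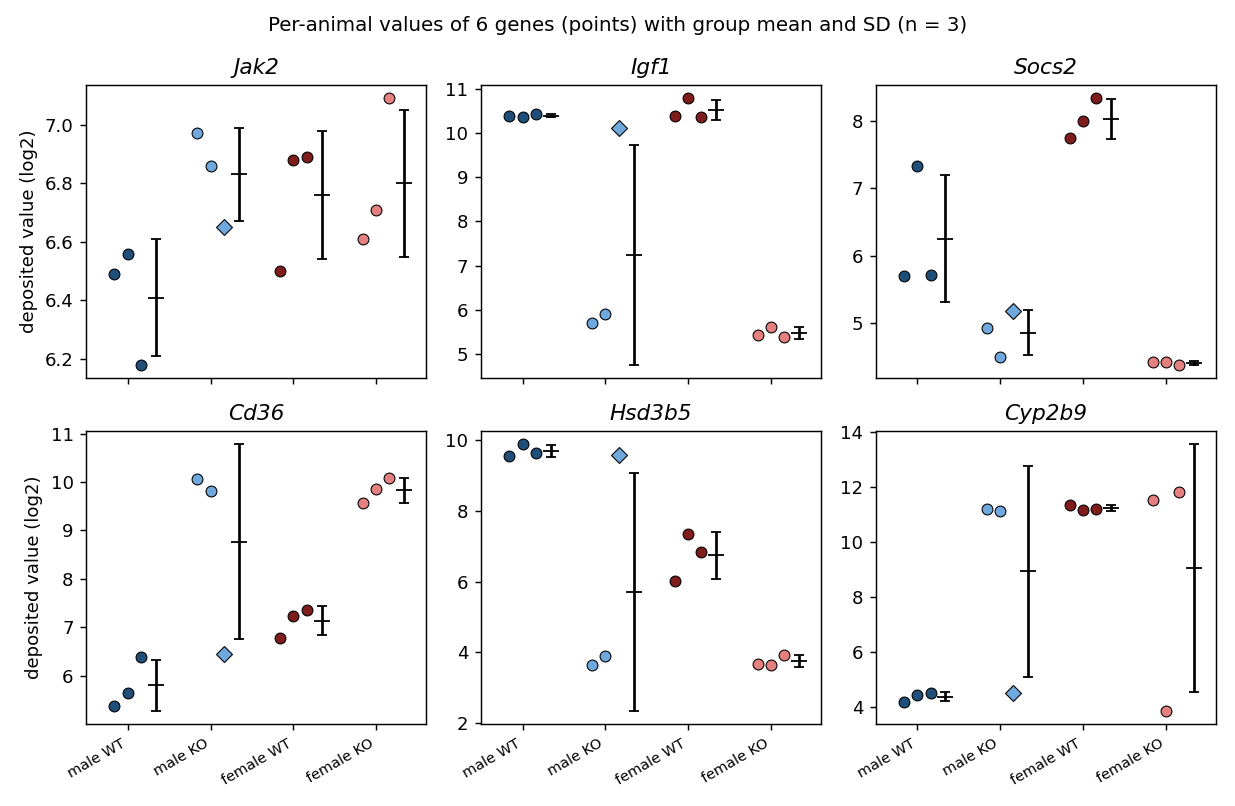
Deposited log2 value (vertical axis) of Jak2, Igf1, Socs2, Cd36, Hsd3b5 and Cyp2b9 in each animal, by group (horizontal axis). Points are animals, bars are the mean ± SD of 3 animals, and the diamond is male KO 207, which reads 10.10 for Igf1 where the other male KO animals read 5.71 and 5.91.

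The first comparison asked what the loss of hepatocyte Jak2 changed in males. Cyp4a14, a fatty acid hydroxylase induced by PPARA, rose by 4.87 (SE 0.63, adjusted p = 0.0138), a 29.2-fold change, with 8.65 to 11.11 in KO and 4.04 to 6.62 in WT. Vnn1, a pantetheinase and another PPARA target, rose by 2.14 (SE 0.32, adjusted p = 0.0302), and Lyve1, a hyaluronan receptor of sinusoidal endothelium, by 0.92 (SE 0.15, adjusted p = 0.0424). Onecut1, which encodes the growth hormone-induced factor HNF6, changed by -2.47 (SE 0.30, adjusted p = 0.0138), from 8.22 ± 0.76 to 5.75 ± 0.36 (SD). Susd4, a complement regulator with male-biased expression, changed by -2.06, the phospholipase-like gene Plcxd2 by -1.25, the transglutaminase gene Tgm1 by -1.18, the acetyltransferase gene Nat8 by -1.0 and the replication factor gene Mcm10 by -0.90. With the predicted gene Gm16551 (-1.48, adjusted p = 0.0279), named because so few genes passed, 10 genes were called, 3 higher and 7 lower in KO, and 1796 had an unadjusted p under 0.05. The calls rested on single animals: limma called 0 genes without male WT 116, male KO 114 or male KO 122, with 1465, 1479 and 1347 genes at an unadjusted p under 0.05. It called 22 without male WT 126, 5 without female WT 119 or female WT 132, 6 without female KO 141, and 475 without male KO 207.

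The classical growth hormone targets were not called in males with all animals, and for several of them male KO 207 read near WT. Igf1, the main endocrine effector of growth hormone (probe set 10365559), read 5.71 in male KO 114, 5.91 in male KO 122 and 10.10 in male KO 207, against 10.39 ± 0.04 (SD) in male WT. Its difference was -3.15 (SE 0.76, adjusted p = 0.136) with all animals and -4.57 (SE 0.14, adjusted p = 1.08e-10), a 23.8-fold change, without male KO 207. Igfals, the subunit that stabilises circulating IGF1, differed by -2.22 (adjusted p = 0.0897) and by -3.04 (adjusted p = 8.77e-07) without that animal. Socs2 and Cish, feedback inhibitors induced by STAT5, differed by -1.38 (adjusted p = 0.122) and -1.08 (adjusted p = 0.143). Their values in male KO 207 were 5.18 and 5.28, close to 4.92 and 5.15 in male KO 114. Male WT 112 read 5.70 and 5.41, so these values do not place male KO 207 with the other KO animals. Socs2 differed by -0.84 without male WT 116 and was called without male KO 207 (-1.54, adjusted p = 0.034), and Cish differed by -0.72 without male WT 116 and was called without male WT 112 (-1.52, adjusted p = 0.00167). Cd36, a fatty acid transporter, read 10.06, 9.82 and 6.44 in the KO animals and 5.80 ± 0.52 (SD) in WT, and its difference was 2.97 (adjusted p = 0.0928), or 4.13 (adjusted p = 1.24e-07) without male KO 207. Pparg, the lipid storage regulator, differed by 1.15 (adjusted p = 0.312), and by 1.67 (adjusted p = 0.00456) without it. The growth hormone receptor gene Ghr (adjusted p = 0.641) and the lipid synthesis genes Fasn, Scd1 and Srebf1 (adjusted p = 0.494, 0.328 and 0.833) were not called in males with or without that animal, but Scd1 was called without male WT 126 (1.83, adjusted p = 0.0279).

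Among the fixed lists, 13 were called in males with camera at the preset correlation, and 0 kept the call with an estimated correlation. Of the 10 genes called over all genes, only Susd4 is on the male-biased list and only Onecut1 on the growth hormone list. Cyp4a14 and Vnn1 are on the list of fatty acid oxidation, and none is on the female-biased, lipid uptake or fatty acid synthesis lists. The 31 male-biased liver genes changed by a mean of -1.63 (adjusted p = 4.76e-29; adjusted p = 0.2 with an estimated correlation), with 27 lower and 2 higher when adjusted over the list alone. The 30 female-biased genes rose by a mean of 1.33 (adjusted p = 1.5e-12; adjusted p = 0.2 with an estimated correlation), with 15 higher and 1 lower when adjusted over the list alone. Genes of fatty acid oxidation and PPARA targets (31 genes) rose by a mean of 0.785 (adjusted p = 9.22e-19) and those of lipid uptake and storage (25 genes) by 0.627 (adjusted p = 1.23e-09), with 13 and 10 genes higher when adjusted over the list alone and adjusted p = 0.2 with an estimated correlation for both. Targets of growth hormone and STAT5 (17 genes) changed by a mean of -0.775 (adjusted p = 9.06e-05; adjusted p = 0.2 with an estimated correlation), with 7 lower and 2 higher when adjusted over the list alone. Fatty acid and triglyceride synthesis (26 genes, mean 0.532, adjusted p = 9.28e-06) had no gene past the threshold when adjusted over the list alone, and adjusted p = 0.356 with an estimated correlation. Its mean was 0.327 without male WT 112, 0.352 without male KO 122, 0.799 without male KO 207 and 0.883 without male WT 126. Without male KO 207 the calls of the growth hormone, male-biased, female-biased and lipid uptake lists held with an estimated correlation (adjusted p = 0.0022, 0.0016, 0.00252 and 0.00137). In that fit 25 male-biased genes were lower and 1 higher, and 15 female-biased genes were higher. Hsd3b5, a male-biased steroid reductase, differed by -5.93 (adjusted p = 7.39e-09), the bile acid and steroid transporter Slco1a1 by -5.54, the female-biased oxidase Hao2 by 4.96, and the sulfotransferases Sult1e1 and Sult2a3, low in WT of both sexes (male means 2.91 and 3.07, female means 3.48 and 3.40), by 5.60 and 5.49.

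The same question in females gave more calls. Sult3a1, a female-specific sulfotransferase, fell from 9.31 ± 0.29 to 3.61 ± 0.56 (SD), a change of -5.70 (SE 0.24, adjusted p = 7.61e-09). Igf1 went from 10.51 ± 0.23 to 5.48 ± 0.13, a change of -5.03 (SE 0.76, adjusted p = 0.00519), a 32.7-fold change. Socs2 changed by -3.62 (SE 0.33, adjusted p = 4.55e-05), Igfals by -3.27 (SE 0.47, adjusted p = 0.00351), Cish by -2.06 (SE 0.27, adjusted p = 0.00158), and the hepatokine Fgl1 by -3.80 (SE 0.50, adjusted p = 0.00164). Slc22a26, a female-biased organic anion transporter, changed by -4.29, Sult3a2 by -4.48, the plasma glycoprotein gene A1bg by -4.05 and the magnesium transporter gene Nipal1 by -2.41. Orm1, an acute phase glycoprotein, changed by -2.34, Myc, a growth regulator, by -1.83, and Psmb8, an immunoproteasome subunit, by -1.06. Gsn, the actin-severing protein gelsolin, rose by 2.23 (SE 0.16, adjusted p = 3.43e-06), the calmodulin-binding Pcp4l1 by 2.85 (SE 0.29, adjusted p = 0.000171), the lipase gene Lpl by 1.24, the HDL receptor gene Scarb1 by 0.80 and the steroid hydroxylase gene Cyp3a25 by 0.72. Each of these 18 genes kept its call in the 12 fits that left out 1 animal, and 46 genes were named by the rule.

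The largest increase in females was that of Sult2a3, by 5.79 (SE 0.97, adjusted p = 0.00949), but its adjusted p was 0.0502 without female WT 132 and 0.0578 without female KO 141. Its values lay at 3.01 to 3.80 in female WT and at 9.09 to 9.36 in female KO. The male KO group, with an SD of 3.13 for this gene, widened the shared spread. These lost calls thus do not show that the change rests on single females. Wfdc21, an acute phase protein gene (-4.68, adjusted p = 0.00969), and G0s2, an inhibitor of triglyceride lipase (1.86, adjusted p = 0.00632), stood at 0.0546 and 0.051 without female KO 141. For Wfdc21 too the SD was larger in male KO (2.53) than in female WT (0.27) and female KO (0.23). Cd36 differed by 2.70 (SE 0.65, adjusted p = 0.077) and Pparg by 1.31 (adjusted p = 0.147). Both were called without male KO 207, which entered this fit only through the shared spread (adjusted p = 4.59e-06 and 0.0143), and Cd36 also without male KO 114 (adjusted p = 0.0455). Ghr (0.04, adjusted p = 0.959), Fasn (adjusted p = 0.936), Scd1 (adjusted p = 0.971) and Srebf1 (adjusted p = 0.841) were not called. In all, 185 genes were called, 75 higher and 110 lower, and 82 of them changed at least 2-fold. The count was 351 without male KO 207, 87 without female WT 119, 94 without female WT 132, 88 without female KO 102, 112 without female KO 131 and 62 without female KO 141.

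Genes of the interferon response and antigen presentation changed in females by a mean of -0.506 over 25 genes (adjusted p = 1.1e-17), the list whose call held with an estimated correlation (adjusted p = 0.0116). The list had 6 genes called lower, and 15 lower when adjusted over the list alone, among them the GTPases Iigp1 (-1.69) and Gbp3 (-1.14) and the chemokine Cxcl9 (-0.90), and Psmb8 as above. The change of Iigp1 was not limited to females, as it was called in males without male KO 207 (-1.44, adjusted p = 0.000266). Gbp3 and Cxcl9 were not lower in male KO (means 5.47 and 5.80) than in male WT (4.94 and 5.68). Cholesterol synthesis genes (20 genes) changed by a mean of -0.678 (adjusted p = 4.12e-15; adjusted p = 0.269 with an estimated correlation). They had 4 genes called lower, the enzymes Sqle (-1.71), Idi1 (-1.39) and Cyp51 (-0.97) and the transfer protein Stard4 (-0.73), and 14 lower when adjusted over the list alone. Growth hormone and STAT5 targets changed by a mean of -1.06 (adjusted p = 3.15e-05; adjusted p = 0.269 with an estimated correlation), with 8 genes called lower and 1, the repressor Bcl6 (2.62), called higher, and with 8 lower and 2 higher when adjusted over the list alone. Fatty acid oxidation genes rose by a mean of 0.516 (adjusted p = 1.48e-17; adjusted p = 0.269 with an estimated correlation). In that list 3 genes were called higher, Pdk4, a brake on glucose oxidation (1.87), the dehydrogenase Acadm (0.88) and the acyltransferase Cpt2 (0.68), and adjusted over the list alone 19 were higher and 1 lower. Lipid uptake and storage genes rose by a mean of 0.597 (adjusted p = 7.08e-07; adjusted p = 0.295 with an estimated correlation), with 3 genes called higher and 10 when adjusted over the list alone, including Fitm1, which promotes lipid droplets (2.44). Of the single genes named here, Psmb8 kept its call in the 12 fits without 1 animal. The others lost theirs in 1 (Cxcl9 and Cpt2) to 9 (Stard4) of these fits, with adjusted p of up to 0.0546 for Cxcl9 and 0.209 for Bcl6 without female KO 141, 0.145 for Sqle and Fitm1 without female WT 132, 0.135 for Cyp51 without female KO 131 and 0.17 for Stard4 without female KO 102. The spread of the males entered these fits. The SD was 1.54 for Bcl6 and 1.0 for Sqle in male WT, and 1.21 for Fitm1 in male KO. In the female groups it was 0.17 to 0.43 for these genes. Their lost calls thus do not show that the changes rest on single females.

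The lists of sex-biased genes gave weaker calls in females. The 30 female-biased genes had a median of 0.0256 and a mean of -0.339, and were called lower (adjusted p = 0.00233; adjusted p = 0.502 with an estimated correlation), a call lost without male KO 207 (adjusted p = 0.252). The mean was -0.224 without female WT 119 and -0.154 without female KO 131. The 31 male-biased genes changed by a mean of -0.505 (adjusted p = 0.0225; adjusted p = 0.594 with an estimated correlation), and were not called without female WT 132 (adjusted p = 0.327) or female KO 131 (adjusted p = 0.0667). Fatty acid synthesis (mean -0.283, adjusted p = 0.04; adjusted p = 0.594 with an estimated correlation) lost its call without female WT 132 (-0.119, adjusted p = 0.45) or female KO 102 (-0.123, adjusted p = 0.457). Acute phase genes (30 genes, mean -0.265, adjusted p = 0.00873; adjusted p = 0.269 with an estimated correlation) lost theirs without female KO 131 (adjusted p = 0.0667), and 4 of them were called lower, Orm1, Orm3, the pentraxin gene Crp (-1.52) and the hepcidin gene Hamp (-0.83). Orm1 kept its call in the 12 fits without 1 animal, and Orm3, Crp and Hamp lost theirs without female KO 141 (adjusted p = 0.0606, 0.0824 and 0.062).

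**Figure D2:**
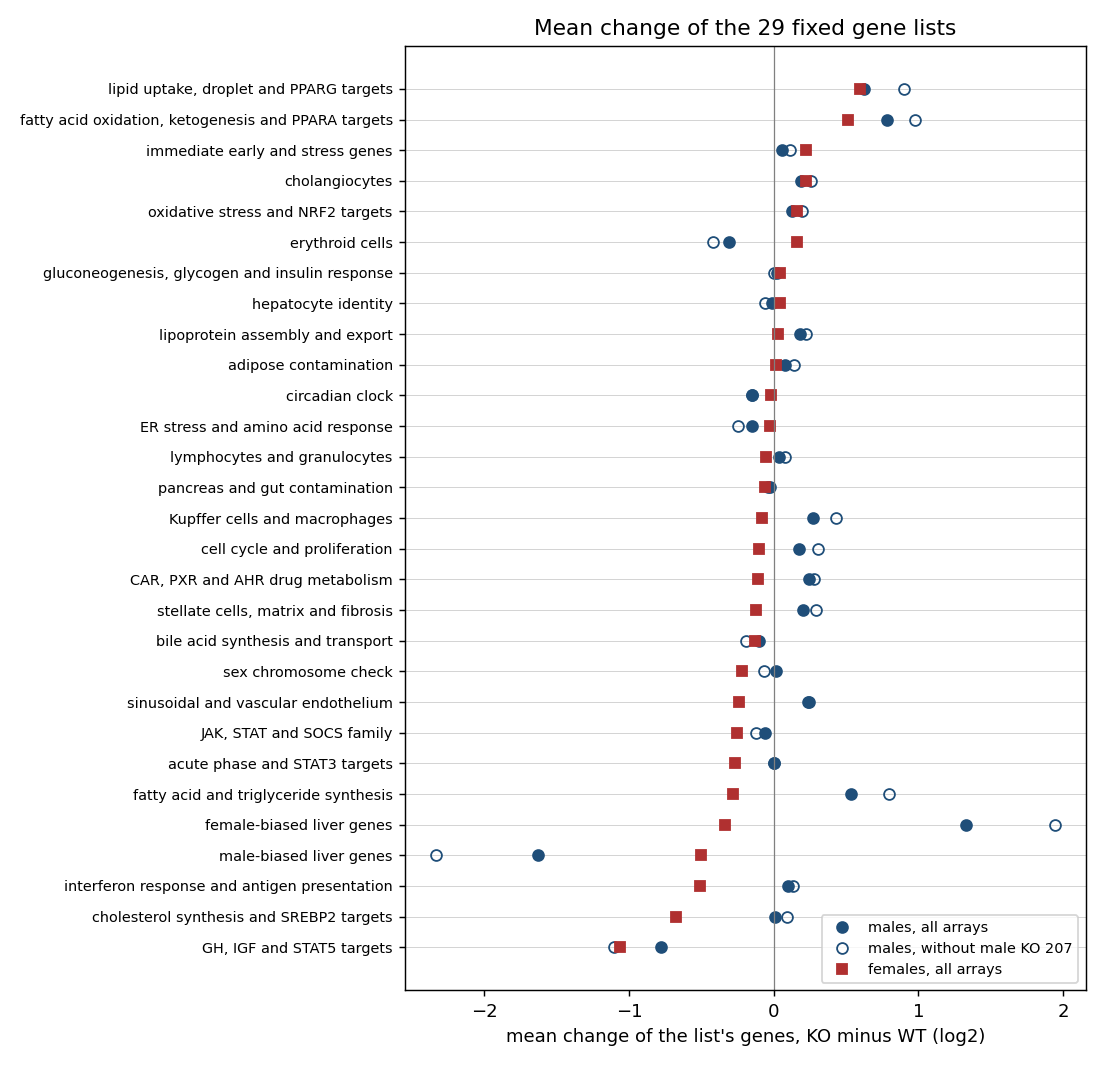
Mean KO minus WT change (log2, horizontal axis) of the 29 gene lists (vertical axis) in males with all arrays (filled circles), in males without male KO 207 (open circles) and in females (squares). The male-biased list lies at -1.63 in males and -0.51 in females, and the interferon list at -0.51 in females.

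The KO effect was also averaged over the sexes, a contrast that gains precision but also calls genes changed in 1 sex only. Onecut1 changed by -2.64 (SE 0.21, adjusted p = 2.02e-05), Socs2 by -2.5 (SE 0.23, adjusted p = 6.09e-05), Igf1 by -4.09 (SE 0.54, adjusted p = 0.00128), Igfals by -2.74 (SE 0.34, adjusted p = 0.000726) and Cish by -1.57 (SE 0.19, adjusted p = 0.000678). Egfr, the epidermal growth factor receptor, changed by -3.41, the serpin pseudogene Serpina4-ps1 by -4.45, Keg1, a glycine acyltransferase-like gene, by -3.30, the P450 gene Cyp2c54 by -3.24 and Kyat3, an aminotransferase gene, by -2.82. Sult2a3 rose by 4.74 (SE 0.68, adjusted p = 0.00215), Cd36 by 2.84 (SE 0.46, adjusted p = 0.00495), Cyp4a14 by 2.95, Sult1e1, an oestrogen sulfotransferase, by 4.28 and Krt23, a keratin of bile duct and injured liver, by 2.14. Of the 58 genes named for this contrast, 34 kept their call in all 12 fits that left out 1 animal, those above among them. In all, 457 genes were called, 266 higher (58.2%) and 191 lower. After quantile normalization it was 231 higher of 459 (50.3%). The count was 893 without male KO 207, 278 without male WT 112, 267 without male WT 116, 238 without male KO 114, 229 without male KO 122, 295 without female WT 119 and 229 without female KO 141. Fatty acid oxidation (mean 0.65, 14 genes called higher and 23 when adjusted over the list alone, adjusted p = 7.08e-25), lipid uptake (mean 0.612, 8 higher and 13 over the list alone, adjusted p = 3.08e-11) and growth hormone targets (mean -0.917, 7 lower and 2 higher, adjusted p = 1.18e-05) were called, with adjusted p = 0.192 with an estimated correlation for each. So were the male-biased genes (mean -1.07, 13 lower and 2 higher, adjusted p = 1.58e-15; adjusted p = 0.245 with an estimated correlation). The female-biased genes, of which 8 were called higher and 5 lower, were not called as a list (adjusted p = 0.23), except without male KO 207 (mean 0.803, adjusted p = 9.37e-07). Cholesterol synthesis (mean -0.334, adjusted p = 3.4e-07), interferon (mean -0.203, adjusted p = 7.48e-06) and oxidative stress genes (mean 0.146, adjusted p = 6.88e-05) were called too, with adjusted p = 0.377, 0.192 and 0.259 with an estimated correlation. For cholesterol synthesis and interferon genes the male means were 0.01 and 0.10 and the female means -0.678 and -0.506. Without male WT 126 the cholesterol mean was -0.177 over the sexes and 0.323 in males (adjusted p = 1.16e-05), and without male WT 112 it was -0.186 in males (adjusted p = 0.0117).

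Calls shared by the sexes were few with all animals and many without male KO 207. Onecut1 (male -2.47, female -2.81), Tgm1 (male -1.18, female -2.05) and Gm16551 (male -1.48, female -1.22) were called lower in both sexes, where 0.0386 shared genes would arise from independent lists (exact one-sided hypergeometric p = 5.63e-06). Both contrasts share each gene's estimate of the spread, and genes are not independent of each other. This p and the expected numbers here are therefore descriptive only. The overlap was 0 without male WT 116, male KO 114 or male KO 122. In the fit without male KO 207, 81 genes were called higher in both sexes (expected 2.26) and 76 lower (expected 1.9), and 3 were called in opposite directions, the proton pump subunit gene Atp6v0d2, the male-biased P450 gene Cyp2d9 and the fatty acid elongase gene Elovl3. These 3 were singled out after their values were seen. Across genes, which are not independent replicates, the male and female changes correlated with r = 0.462. Of the 185 genes called in females, 168 had the same sign in males, with a median ratio of the male to the female change of 0.495, or 0.745 over the 351 genes called without male KO 207. Choosing genes by their call in females favours large female changes and lowers both ratios. They therefore do not show that males responded less.

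Whether the effect of the deletion differed between the sexes was tested as the male change minus the female change. Sult3a1 gave 5.52 (SE 0.35, adjusted p = 1.48e-06), Sult3a2 4.55 (SE 0.26, adjusted p = 8.29e-07) and Slc22a26 3.87 (SE 0.29, adjusted p = 1.08e-05). These genes were high in female WT (9.31, 6.91 and 9.09) and had means of 2.43 to 4.80 in the other groups. With male WT already at 2.62, 2.43 and 4.45, a fall in males could hardly be measured. For these genes the contrast thus cannot tell a different response from a low starting level in males. Fmo2, a female-biased monooxygenase, gave 2.05 (SE 0.19, adjusted p = 0.000167), Gbp7, an interferon-induced GTPase, 1.79 (SE 0.20, adjusted p = 0.00153), Atp6v0d2 2.18 and Nipal1 1.96. Gsn gave -1.88 (SE 0.23, adjusted p = 0.00275), with 9.29 ± 0.44 in female KO and 6.66 to 7.05 as the means of the other groups. Pcp4l1 (-2.77, adjusted p = 0.0166), the sulfotransferase Sult1c2 (1.04) and the glutamate receptor gene Grid1 (0.91) lost their calls in 5, 9 and 9 of the 12 fits without 1 animal, with up to 0.0789 for Pcp4l1 without female KO 141. With these, 11 genes were called, 9 positive and 2 negative. The count was 58 without male KO 207, where Elovl3 (-4.62) and the oxysterol hydroxylase gene Cyp7b1 (-3.76) were called too. Socs2 (2.23, adjusted p = 0.208) and Igf1 (1.89, adjusted p = 0.999) were not called, but Socs2 was without male WT 116 (2.77, adjusted p = 0.000216).

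As lists, 12 differed in their KO effect between the sexes at the preset correlation. The interferon list gave a mean of 0.605 (adjusted p = 7.29e-20) and held with an estimated correlation (adjusted p = 0.00824). Female-biased genes gave 1.67 (adjusted p = 3.13e-24), with 5 called positive and 13 when adjusted over the list alone, and sinusoidal and vascular endothelium markers gave 0.484 (adjusted p = 2e-14), both with adjusted p = 0.088 with an estimated correlation. Male-biased genes gave -1.12 (adjusted p = 2.39e-14; adjusted p = 0.247 with an estimated correlation), cholesterol synthesis 0.688 (adjusted p = 2.35e-12; adjusted p = 0.285 with an estimated correlation) and fatty acid synthesis 0.815 (adjusted p = 2.46e-08; adjusted p = 0.319 with an estimated correlation). Without male KO 207, 7 lists were called with an estimated correlation, among them the male-biased (mean -1.82) and female-biased differences (adjusted p = 0.00294 and 0.00154).

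The sexes were also compared within each genotype, since the pattern of growth hormone secretion sets much of the sex difference of the liver. In WT, Elovl3 was higher in males by 4.96 (SE 0.71, adjusted p = 0.00414), Cyp2d9 by 2.65 (SE 0.34, adjusted p = 0.00139), the adipokine gene Serpina12 by 2.44, the P450 gene Cyp2u1 by 2.17 and the haem synthesis gene Alas2 by 2.13. Higher in females were Sult3a1 (male minus female -6.69, SE 0.24, adjusted p = 5.31e-10), Cyp4a14 (-5.53, SE 0.63, adjusted p = 0.000507), Slc22a26 (-4.64), Sult3a2 (-4.48), Atp6v0d2 (-2.84) and the thioesterase Acot3 (-2.5). These kept their calls in all 12 fits without 1 animal. Socs2 was higher in females (-1.77, adjusted p = 0.024), a call lost in 5 of those fits, with adjusted p = 0.124 without male WT 112. Igf1, Igfals and Cish did not differ (adjusted p = 0.982, 0.925 and 0.321). In WT, 101 genes were called, 36 higher and 65 lower in males. The count was 194 without male KO 207, 51 without male WT 112, 42 without male WT 116, 58 without female WT 119 and 66 without female WT 132. The male-biased list was higher by a mean of 1.85, with 10 genes called (adjusted p = 1.3e-34; adjusted p = 0.048 with an estimated correlation), and the female-biased list differed by a mean of -2.33, with 14 called (adjusted p = 2.01e-45; adjusted p = 0.0334 with an estimated correlation). The interferon list was higher in females (mean -0.319, adjusted p = 2.36e-08; adjusted p = 0.048 with an estimated correlation), and so was the cholesterol synthesis list (mean -0.631, adjusted p = 3.62e-14; adjusted p = 0.196 with an estimated correlation). With an estimated correlation 4 lists were called in WT, but 2 without male KO 207. The male-biased, female-biased and interferon lists thus did not all keep their calls in that fit.

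In KO animals 6 genes differed between the sexes: the sex-linked genes Eif2s3y (4.50), Uty (3.39), Kdm5d (2.14) and Xist (-6.31), and Gsn (-2.27, adjusted p = 3.24e-06) and Pcp4l1 (-2.83, adjusted p = 0.000306), both lower in males. Each kept its call in the 12 fits without 1 animal. Without male KO 207 the count was 14, among them the lipocalin gene Lcn2 (1.28), the lipid droplet gene Cidec (1.39) and the retinoic acid hydroxylase gene Cyp26a1 (-2.53). The list of 30 female-biased genes was lower in KO males (mean -0.654, adjusted p = 3.64e-11; adjusted p = 0.198 with an estimated correlation), and had a mean of -0.0428 without male KO 207 (adjusted p = 0.008; adjusted p = 0.25 with an estimated correlation). Male-biased genes were higher by 0.731 (adjusted p = 9.5e-10; adjusted p = 0.357 with an estimated correlation), a call lost without male KO 207 (0.033, adjusted p = 0.555). The interferon list was higher in KO males by 0.287 (adjusted p = 7.61e-11; adjusted p = 0.0313 with an estimated correlation). The sex index, the male-biased mean minus the female-biased mean, was 2.87 ± 0.203 (SD) in male WT, -1.31 ± 0.504 in female WT and -1.47 ± 0.274 in female KO. Among male KO it was -1.42 in 114, -1.38 in 122 and 2.53 in 207. WT sexes differed by 4.18 with the smallest p this design allows (exact permutation, two-sided p = 0.1), and KO sexes by 1.39 (exact permutation, two-sided p = 0.4). Without male KO 207 the difference between the KO sexes was 0.076.

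**Figure D3:**
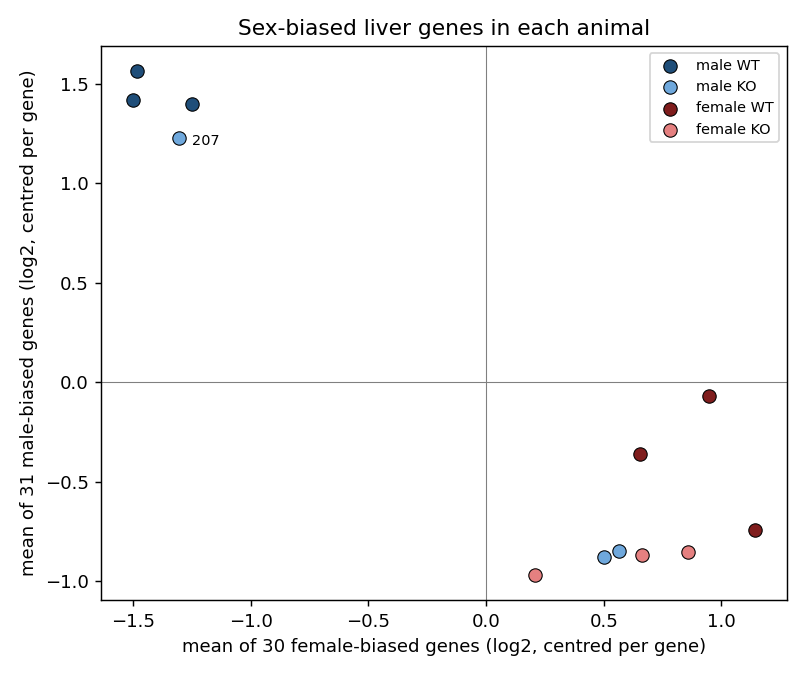
Mean centred log2 value of the 30 female-biased genes (horizontal axis) against that of the 31 male-biased genes (vertical axis), 1 point per animal, coloured by group. Male KO 114 and 122 lie beside the females and male KO 207 lies beside male WT.

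In males the endothelial markers rose by a mean of 0.247 (17 genes, adjusted p = 4.82e-06; adjusted p = 0.242 with an estimated correlation), with Lyve1 called, and the Kupffer cell and macrophage markers by 0.271 (25 genes, adjusted p = 5.46e-06; adjusted p = 0.319 with an estimated correlation), and both kept their calls in the 12 fits without 1 animal. The endothelial mean was 0.155 without male WT 116, and the macrophage mean 0.153 without male KO 114 and 0.429 without male KO 207. Stellate cell and matrix genes (0.202, adjusted p = 0.000174; adjusted p = 0.274 with an estimated correlation) lost their call in males without male KO 114 (0.097, adjusted p = 0.0953), as did oxidative stress genes (0.129, adjusted p = 0.00171; adjusted p = 0.274 with an estimated correlation), with a mean of 0.074 (adjusted p = 0.0592), and of 0.198 without male KO 207. Cell cycle genes (0.176, adjusted p = 0.013; adjusted p = 0.409 with an estimated correlation) lost it without male WT 126 (adjusted p = 0.0562) or male KO 114 (mean 0.054, adjusted p = 0.586), and had a mean of 0.304 without male KO 207. ER stress genes (-0.152, adjusted p = 0.000638; adjusted p = 0.274 with an estimated correlation) lost it without male WT 126 (mean -0.085, adjusted p = 0.058) or male KO 122 (mean -0.052, adjusted p = 0.0827), and had a mean of -0.249 without male KO 207. The 6 erythroid genes (-0.309, adjusted p = 0.016; adjusted p = 0.2 with an estimated correlation) lost it without male WT 112 (adjusted p = 0.0532) or male KO 122 (adjusted p = 0.0749). In females the endothelial markers changed by a mean of -0.237 (adjusted p = 8.06e-06; adjusted p = 0.295 with an estimated correlation) and oxidative stress genes rose by 0.164 (adjusted p = 0.00116; adjusted p = 0.298 with an estimated correlation). Stellate cell genes (-0.121, adjusted p = 0.0101; adjusted p = 0.489 with an estimated correlation) lost their call in females without female KO 141 (0.0684). Drug metabolism genes were called higher in females (adjusted p = 0.0101; adjusted p = 0.298 with an estimated correlation) at a median of 0.147 and a mean of -0.107, which was 0.037 without female KO 131, in which Cyp2b9 read 3.87. They lost the call without female KO 141 (mean -0.233, adjusted p = 0.109). The 4 sex-linked genes measured (mean -0.22, adjusted p = 0.0225; adjusted p = 0.406 with an estimated correlation) lost theirs without female WT 147 (0.082) or female KO 131 (0.0667). Of these, Eif2s3y, Kdm5d and Uty are Y-linked and give only background in females, so that call cannot show an effect of the deletion.

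With all animals no call was made in either sex for the JAK, STAT and SOCS family (male mean -0.06, adjusted p = 0.872; female mean -0.25, adjusted p = 0.0874), in which Socs2 and Cish were called in females. The same held for lipoprotein assembly (adjusted p = 0.0522 in males and 0.119 in females), bile acid synthesis and transport (0.595 and 0.226), gluconeogenesis (0.157 and 0.274), the circadian clock (0.0737 and 0.724) and hepatocyte identity genes (0.872 and 0.274). Bile acid genes had medians of 0.12 and 0.06 and means of -0.10 and -0.13 in males and females. Lymphocyte and granulocyte markers (0.61 and 0.262), bile duct markers (0.157 and 0.357), pancreas and gut genes (0.583 and 0.224), adipose genes (0.157 and 0.724) and immediate early genes (0.834 and 0.229) were not called either. In females Krt23 (2.56) among the bile duct markers and Myc among the immediate early genes were called all the same. Krt23 lost its call in 4 of the 12 fits without 1 animal, with adjusted p = 0.075 without female KO 141. Its SD was 0.27 in female WT, 0.22 in female KO and 1.41 in male KO, which entered the shared spread. Males had no call for acute phase (adjusted p = 0.595), interferon (0.0803), cholesterol synthesis (0.872) or drug metabolism genes (0.114). Females had none for macrophage markers (0.192), cell cycle (0.0555), ER stress (0.43) or erythroid genes (0.361). Fits without 1 animal called some of these lists. In males these were the interferon list without male WT 112, male WT 116 or male KO 122 (adjusted p = 0.0408, 0.0489 and 0.0243), the clock without male WT 112 or male KO 114 (0.0486 and 0.0338), lipoprotein assembly without male WT 126 (0.00629), adipose genes without male KO 207 (0.0286), and gluconeogenesis and drug metabolism without male KO 122 (0.0455 and 0.00661). Immediate early genes had a male mean of -0.269 without male KO 114 (0.0311) and of 0.329 without male KO 122 (0.00713), and cholesterol synthesis is given above. In females the JAK list was called without male WT 116, female WT 119 or female KO 141 (0.0425, 0.0229 and 0.0145), cell cycle without male KO 114, male KO 207 or female WT 119 (0.0368, 0.0471 and 0.00844), and macrophage markers without female WT 132 (0.0274).

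Genes near Jak2 were counted because strain differences can travel with a floxed allele in a mixed background. Of 127 tested genes within 10 Mb of Jak2 (neighbours taken from GRCm38.p6), 5 (3.94%) were called for the mean over the sexes, against 452 of 19728 others (2.29%), an odds ratio of 1.75 (Fisher's exact test, p = 0.221). In females it was 2 (1.57%, odds ratio 1.71, Fisher's exact test, p = 0.332), and none of the 10 genes called in males lay there. Without male KO 207 it was 10 for the mean (7.87% against 4.47%, odds ratio 1.83, p = 0.0802), 5 in females (3.94% against 1.75%, odds ratio 2.3, p = 0.0751) and 5 in males (3.94% against 2.38%, odds ratio 1.68, p = 0.234), each by Fisher's exact test.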

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

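The regroupings of the samples were planned, and the tests on male KO 207, on the Cyp2b genes and on the interferon list were chosen only after those results had been seen.

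Genes whose KO effect differed between the sexes in the tested interaction are listed first. The male change minus the female change was 5.52 for Sult3a1, 4.55 for Sult3a2, 3.87 for Slc22a26, 2.18 for Atp6v0d2, 2.05 for Fmo2, 1.96 for Nipal1, 1.79 for Gbp7, 1.04 for Sult1c2 and 0.91 for Grid1. It was -2.77 for Pcp4l1 and -1.88 for Gsn. Sult3a1, Slc22a26, Atp6v0d2, Fmo2 and Nipal1 belong to the fixed list of female-biased genes, and in each the female WT mean was the highest of the 4 groups. For Sult3a1, Sult3a2 and Slc22a26 male WT already read low (means 2.62, 2.43 and 4.45), so a fall in males could hardly be measured. Gsn and Pcp4l1 stood out in female KO and not in male KO, and this did not depend on male KO 207, whose removal left Gsn at -2.32 and Pcp4l1 at -2.78 between the KO sexes.

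The same contrast called 12 lists at the preset correlation. The mean KO effect in males minus that in females was -1.12 for male-biased genes, 1.67 for female-biased genes, 0.81 for fatty acid and triglyceride synthesis, 0.69 for cholesterol synthesis and 0.6 for interferon response and antigen presentation. It was 0.48 for endothelium, 0.35 for Kupffer cells and macrophages, 0.32 for stellate cells and matrix, 0.28 for cell cycle, 0.24 for the 4 sex-linked genes, -0.13 for ER stress and -0.47 for erythroid cells. Females lack the Y-linked genes Eif2s3y, Kdm5d and Uty, so their female values (group means of 2.71 to 3.65) are background. The call of the sex-linked list thus cannot show a sex difference in the KO effect. With an estimated correlation the interferon list alone kept its call with all animals, and 7 lists were called without male KO 207. ER stress and the sex-linked genes lost theirs in 6 and 7 of the 12 fits without 1 animal. The mean for ER stress was -0.061 without male WT 126, -0.029 without male KO 122 and -0.225 without male KO 207, and that for sex-linked genes 0.124 without male WT 112 and 0.152 without male KO 207. Without male KO 114 it was 0.155 for cell cycle and 0.233 for Kupffer cells and macrophages, and without male KO 207 -1.82 for male-biased genes.

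Outside the genes compared in the report there were 13768 array features, with several gene symbols or none. In the mean over the sexes 37 of them differed between KO and WT when all 35557 features were tested together, 17 of them with several symbols, against 183 calls in all. They were given no gene name here.

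Regroupings of the arrays showed how far the counts of called genes stand out. With 6 arrays there are 10 splits, too few for a share under 0.05. Among them 2 gave as many calls as the 10 found in males, and the highest other gave 34, by setting male WT 112, male WT 116 and male KO 207 against the rest, which points to a structure of the samples. Among females 1 split, the real one, reached 185, with 1 as the highest other count. The same was found for the sexes in WT (101 calls, 1 split, highest other 1) and in KO (6 calls, 1 split, highest other 1). For the mean over the sexes 1 of 100 splits within the sexes reached 457 calls, the real one, and the highest other had 364. This share is under 0.05, which argues against chance for this count but does not exclude it. For the genes called in both sexes it was 2 of 100 splits (3 genes, highest other 3). That share is under 0.05 as well, but a wrong grouping gave as many shared genes as the real one, so chance is not excluded there. For the difference between the sexes 5 of 100 splits gave at least the 11 calls of the real one, itself included, which by the rule set for this test fits chance. The highest other count was 457, from the split that exchanges the female labels and so turns the difference into the mean, a structure of the samples. Since exchanged labels carry the KO effect of both sexes into the difference, this test is not informative and the question stays open.

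Male KO 207 read near male WT for most genes that set the other male KO animals apart. A swap with a male WT array is argued against: along the change that the females define over 126 genes, the highest male WT animal stood at 6.22%, where male KO 114 and 122 stood at 77.7% and 73.5%. Deletion in part of the hepatocytes, as a plain mixture of cells, stays open. The share of the KO level was 27.1% over 98 genes that fell and 5.41% over 87 genes that rose. The difference was 21.7 percentage points (SE 5.48), where a mixture would give equal shares if array values were proportional to RNA. Values of dim genes are compressed, and the SE was taken over genes, which are not independent replicates. This difference therefore cannot decide the question. A wrong genotype label or a liver without the deletion remains possible, since the animal stood at 13.3% with 3 male WT animals at -3.19% to 6.22% (SD 5.38), and too few WT males were measured to tell. Single values, chosen after they were seen, went both ways and cannot decide the question. Onecut1 at 6.16 and Cyp4a14 at 8.65 were nearer to the other male KO animals. Male WT read 7.39 to 8.89 and 4.04 to 6.62 for these genes. Igf1 at 10.10 and Hsd3b5 at 9.59 were near the male WT means of 10.39 and 9.70. A biological difference between animals was not tested.

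The neighbouring P450 genes Cyp2b9, Cyp2b13 and Cyp2b10 were low in female KO 131 (3.87, 3.38 and 6.61) and high in female KO 102 (11.51, 10.58 and 9.69) and 141 (11.80, 10.72 and 9.47). A wrong genotype label is argued against, since that animal stood at 106% of the KO change of the other female KO animals over 183 genes. The probe set of Rnf170, singled out after its values were seen and a gene with a pseudogene inside Cyp2b13 in GRCm38.p6, was low in the same animal (6.34, against 8.82 and 9.66). Lower activity of the receptor CAR, which induces these genes, stays open: the 22 other genes on the list of CAR, PXR and AHR drug metabolism deviated by a median of -0.02 and at the lowest by -0.66, but many of them answer to other receptors. A change local to the gene cluster on chromosome 7 cannot be told apart from others, since 0 further genes were lower by 2.5 log2 or more in this animal than in both others, and a strain variant or cross-hybridisation of the related genes was not tested.

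Interferon response genes were lower in female KO than in female WT, with the mean centred log2 values of the 3 WT animals at 0.225 to 0.301 and those of the 3 KO animals at -0.334 to -0.196. Fewer macrophages and lymphocytes are argued against as the main source, because the 48 genes of these lists had a median change of -0.07, against -0.44 for the interferon list. The SE of 0.03 of that median was taken over genes, which are not independent replicates. Per animal the macrophage means overlapped, at -0.048 to 0.247 in female WT and -0.116 to 0.073 in female KO. Since values of dim genes are compressed, a loss of cells with dim markers could be missed. A smaller share of endothelial cells stays open as part of the change, because endothelial markers changed by a mean of -0.237 and stellate cell genes by -0.121 in the same animals. A single female WT animal with a high response is argued against too, since leaving out each of them left a mean change of -0.49 or further from 0, against -0.51 with all. A lower interferon response of the hepatocytes was not separated from this, and an effect of housing or infection that differed between the groups was not tested.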

How the results depend on the processing

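All alternatives were planned, except those that apply the list tests, the naming rule and the overlap to the fit without male KO 207. No gene named and called with all animals changed sign under any of them, while 35 values of genes that were called neither with all animals nor in the alternative did. Values that answer a comparison stayed on their side of the threshold, within 1.5 times the count or within their spread in 229 cases, moved in 72 and became stronger in 1.

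Leaving out 1 animal at a time moved most counts of called genes. They ranged from 0 to 475 in males (10 with all animals), from 62 to 351 in females (185), from 229 to 893 for the mean over the sexes (457), from 8 to 58 for the difference between the sexes (11), from 42 to 194 for the sexes in WT (101), from 6 to 14 for the sexes in KO (6) and from 0 to 157 for genes called in both sexes (3). The highest value of each came without male KO 207, and the fit without it kept all of the calls, in the same direction, in every contrast except the mean over the sexes, where 448 of 457 were kept. The 0 in males and in both sexes came without male WT 116, male KO 114 or male KO 122. Lists called between the KO sexes ranged from 8 to 14 (13). The difference of the sex index between the KO sexes ranged from 0.076 to 2.05 and the odds ratio near Jak2 from 1.18 to 2.82. Each of these fits has 1 animal fewer, and otherwise the cause was not tested.

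Array weights gave 220 called genes in males, 718 for the mean over the sexes, 18 for the difference, 170 for the sexes in WT and 62 in both sexes, and an odds ratio near Jak2 of 2.3 (Fisher's exact test, p = 0.0261), the only alternative with that ratio past 0.05; the cause was not tested. A robust variance prior gave 5 in males and 1 in both sexes, and 57 of the 164 calls of named genes were lost under it. The cause was not tested. Testing each of the 35557 probe sets on its own gave 0 in males (limma, 2639 at an unadjusted p under 0.05), 70 in females, 183 for the mean, 7 for the difference, 39 for the sexes in WT and 0 in both sexes; more tests are corrected for, and other causes were not tested. With only the arrays compared, limma called 0 in males (1597 at an unadjusted p under 0.05), 343 in females and 0 in both sexes. These fits have 4 residual degrees of freedom in place of 8, and the female one leaves out the spread of the male KO group; which of these was the cause was not tested. A 2-fold minimum left 82 genes in females, 101 for the mean and 59 for the sexes in WT, and an adjusted p under 0.01 left 0 in males, 66 in females, 152 for the mean, 47 for the sexes in WT and 0 in both sexes, as stricter thresholds must give fewer.

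Lists called depended on the set test. An estimated correlation left 0 of 13 lists in males, 1 of 14 in females, 0 of 10 for the mean, 1 of 12 for the difference, 4 of 14 for the sexes in WT and 2 of 13 for the sexes in KO. Without male KO 207 an estimated correlation gave 4, 3, 4, 7, 2 and 2 lists in this order, so these counts depend on that animal. The rotation test fry gave 0, 1, 4, 1, 6 and 2 lists in the same order, and 13, 8, 12, 8, 7 and 4 without male KO 207. Its mixed form gave 20 for the mean, 3 for the difference and 5 for the sexes in KO. These tests ask other questions than camera does or allow for more correlation between genes.

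Of single list tests, 2652 kept their side of the threshold, 223 became weaker, 80 stronger and 3 reversed, and these 3 were not called with all animals but were called in the other direction. Cholesterol synthesis genes in males had a mean of 0.323 (adjusted p = 1.16e-05) without male WT 126, and ranged from -0.186 to 0.323 over the fits without 1 animal. Immediate early genes had a mean of -0.269 (adjusted p = 0.0311) in males without male KO 114, in a range of -0.269 to 0.329, and of -0.387 (adjusted p = 0.0153) between the KO sexes without the same animal, in a range of -0.387 to 0.211. The cause was not tested. Of values of single named genes, 7540 kept their side of the threshold, 663 became weaker and 322 stronger.

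Quantile normalization, median centring, leaving out the dimmest genes, a trended prior and the mean of a gene's probe sets kept all counts of called genes within 1.5 times. Detection calls were not used here, so the values of dim genes cannot be set against the background of the arrays.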

Other observations

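The tests in this part were all chosen after the results had been seen.

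Some genes, singled out after their values were seen, varied between animals of the same group. Gstp3, a glutathione transferase gene, read 10.99 to 11.37 in male WT 112, male KO 114, female WT 147 and female KO 102, and 6.84 to 8.89 in the other animals. Ctse, a protease gene, read 8.95 in male KO 122 and 9.23 in female KO 131, and 4.24 to 6.29 elsewhere. Sult2a6, a sulfotransferase gene, read 7.25 in female KO 141 and 2.49 to 3.16 elsewhere.

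It was asked whether male KO livers take on the female WT level of sex-biased genes. Over 61 sex-biased genes the share nearer to the female WT mean than to the female KO mean was 19.7% in male KO 114, 21.3% in male KO 122 and 59% in male KO 207. The middle value of 21.3% argues against it. The root mean square distance of male KO 114 was 0.60 log2 to female KO and 2.11 to female WT, and that of male KO 122 was 0.68 and 1.92. Male KO 207 lay at 0.57 from male WT. In male KO 114 and 122 the deletion may thus bring these genes to the level of female KO and not to that of female WT, a hypothesis found and tested on the same 61 genes.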
